A study of Mus musculus with 2 samples.

How the data were processed

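CTCF ChIP-seq was run on forebrain of postnatal day 0 mice of strain B6NCrl, pooled from several dissections. Per the labels, the 2 libraries are biological replicates 1 and 2 of 1 group, and both cite the same biosample and donor. An experiment that the labels name as a possible control was not used here. The files were peak lists on the mm10 assembly, per the labels: 1 list called on each replicate, 1 called on both together, and the optimal and conservative lists that passed an irreproducible discovery rate (IDR) threshold. The aligner, the peak caller and the read depth are not given in the sources used here.

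Each deposited peak list gave a signal value per peak, the strength as the authors' peak caller wrote it. Its scale was not stated, so it was used to rank, filter and describe peaks and compared between replicates only after centring on the median ratio. The deposited lists also gave −log10 of a q-value, and the authors' IDR lists gave a score that ran from 537 to 1000 and stood at 1000 for 77.1% of the optimal list. The summit offset was used to place each summit. Each of the replicate and pooled lists held exactly 300000 peaks, so the weakest entries were set by a fixed length of the list. Every optimal and conservative peak was found in the pooled list.

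Genome sequence was GRCm38 (mm10), and every peak end lay within its chromosome lengths. Gene models were the GENCODE M21 basic set, and TSSs the 5′ ends of its transcripts. The 8 optimal-list peaks on unplaced contigs were left out of analyses that need sequence or annotation. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and pysam 0.24.0, with samtools 1.23.1 to index the genome and matplotlib 3.10.9 for the figures.

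The comparisons, tests, alternatives, gene lists, regions and the rule for named genes were set before the data were examined, except where stated. Named were the preset regions, up to 3 genes per list with the highest signal value within 1 kb of a TSS, the 10 strongest peaks, the 10 protein-coding genes with the strongest promoter peak and the 5 peaks with the largest replicate difference in each direction. Some items this rule selects were left out of the text. Other genes were named after their values were seen: Ctcf, Yy1, Zfp143 and the single sites of the preset regions. Replicate overlap counted summits within 100 bp among as many top peaks of each replicate as the optimal list holds, with chance from 1000 circular shifts along each chromosome. A replicate's signal value at an optimal-list peak was that of its strongest overlapping peak. Summits were assigned to promoter (1 kb), exon, intron or intergenic DNA in that order. Chromosome density used bases other than N. The motif CCASYAGRKGGCRS, 14 bases long, was searched on both strands with at most 2 mismatches within 50 bp of the summit and in windows 1000 bp away. Differences of mean log2 signal value were tested with 100000 permutations, gene lists with 2-sided Fisher's exact tests against all other protein-coding and long noncoding RNA genes (32049 genes in all), and regions against 10000 random windows holding a TSS, as a description. The protocadherin list followed its written rule and so left out the Pcdhga and Pcdhgb genes. Adding them gave 40 of 56 genes with a site. Of the 22 names asked for in the CTCF and cohesin list, 20 were in the annotation.

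Alternatives were the conservative list, the stronger part of the optimal list, each replicate alone, other windows, distances, motif thresholds and overlap rules, and a GC-matched background. Chosen after seeing the data were the split of promoter peaks by motif, protein-coding genes only, 1 TSS per gene, the wider protocadherin list and the nearest summit in each replicate. With 1 TSS per gene, 7 of 39 Hox genes had a site, against 6 in the main setting. The position used there was therefore not always among the transcript 5′ ends of the main setting. No comparison between conditions was possible with 1 group. The statistics were tested on simulated data: the motif scan found 100% of planted matches among 5000 windows and a match in 2.3% of random windows without one. A simulated replicate overlap of 70.6% came back as 70.7%, a planted difference of 0.5 as 0.48, and the genome-wide scan found 100% of 1000 planted matches. The gene list test called 99.35% of 2000 enriched lists and 4.25% of 2000 unchanged ones. Those lists held independent genes, were longer than most preset lists, had a large planted excess and were called without adjustment. They do not show how often a real difference in a small list would be missed.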

Results

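CTCF is a zinc-finger protein that binds a long DNA motif and, together with cohesin, holds chromatin loops in place. Its binding sites were mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in forebrain of mice on postnatal day 0. The tissue was pooled from several dissections. The series held 1 group of 2 libraries, called replicate 1 and replicate 2 here, and no second condition. Each replicate had 300000 called peaks, and a further list of 300000 peaks was called on both libraries together. The median signal value was 4.78 in replicate 1 and 4.18 in replicate 2, and the highest were 352 and 314. At a q-value of 0.05, 118097 peaks of replicate 1 and 123288 peaks of replicate 2 remained. Read depth was not given in the sources used here, so peak signal values, which are the authors' own and whose scale was not stated, were the only measure of strength. The optimal list had 56470 peaks, of which 56462 lay on chromosomes 1 to 19, X and Y, and was the main list of bound sites. Intervals cover counting error only, and tests across peaks or genes treat as separate units sites that are not independent replicates.

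The 10 strongest CTCF sites of the newborn forebrain lay mostly away from promoters, as did most sites of the whole optimal list. The site with the highest signal value, 662, was in an intron of Fam129b (chromosome 2, 32912425 to 32912782, mm10), 36508 bp from the nearest transcription start site (TSS). It held the sequence CCACTAGGTGTCGC, 1 mismatch from the CTCF motif, at 32912631 to 32912644. The next was an intergenic site 40793 bp from the TSS of Glrx3 (chromosome 7, 137478243 to 137478621), with a signal value of 627. A site in a coding exon of Gm16253 and an intron of Polr3gl (chromosome 3, 96580205 to 96580564) had a signal value of 627 as well. Pink1, a mitochondrial kinase gene, carried an intronic site of 610 whose motif, CCACTAGGTGGCGC, had 0 mismatches (chromosome 4, 138319551 to 138319892). Gdf15, which encodes a stress-induced cytokine, had a site of 610 in a coding exon (chromosome 8, 70629723 to 70630107). The remaining members of the 10 strongest were the promoter of Adprhl2, introns of Col18a1, Pick1 and 2900026A02Rik, and an intergenic site 53579 bp from the TSS of Snx19. All 10 had a motif match, and the signal value at Fam129b was 352 in replicate 1 and 314 in replicate 2.

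Among protein-coding genes, Adprhl2 had the highest signal value within 1 kb of a TSS, 622, with the summit 63 bp from it (chromosome 4, 126321585 to 126321984). Nipsnap2 followed with 580 and Med4, a subunit of the Mediator complex, with 576. Rrp1 had 568, Disp3 554, Gins4, a subunit of the GINS replication complex, 552, and Lsm11 535. Top1mt, the mitochondrial topoisomerase gene, had 534, Hjurp, the chaperone of the centromeric histone, 532, and Rab2b 514. Rab2b was the one gene of these 10 with no motif match within 50 bp of the summit.

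The 2 replicates found the same strong sites, and the sites they did not share were weak. Of the top 56462 placed peaks of replicate 1, 84.2% (Wilson 95% interval 83.9 to 84.5%) had a summit within 100 bp of one among the top peaks of replicate 2. Circular shifts of the positions gave 0.465% ± 0.0306 (SD over 1000 shifts), and p was 0.001 by this permutation, the smallest it can give. All of the 5000 strongest replicate 1 peaks lay within 100 bp of a replicate 2 summit, whereas 9.67% of those ranked below 200000 did. Across the 56235 optimal-list peaks with a called peak in both replicates, Spearman's rho of the signal values was 0.937 and Pearson's r of their log2 values 0.935. This correlation is across sites. It was taken over a list selected for reproducibility in these same 2 libraries, so a high value was partly built in. Both libraries cite the same pooled tissue, so the spread between them may be technical. The share of shared summits was 91.7% for the top 10000 and 35.1% for all called peaks.

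**Figure D1:**
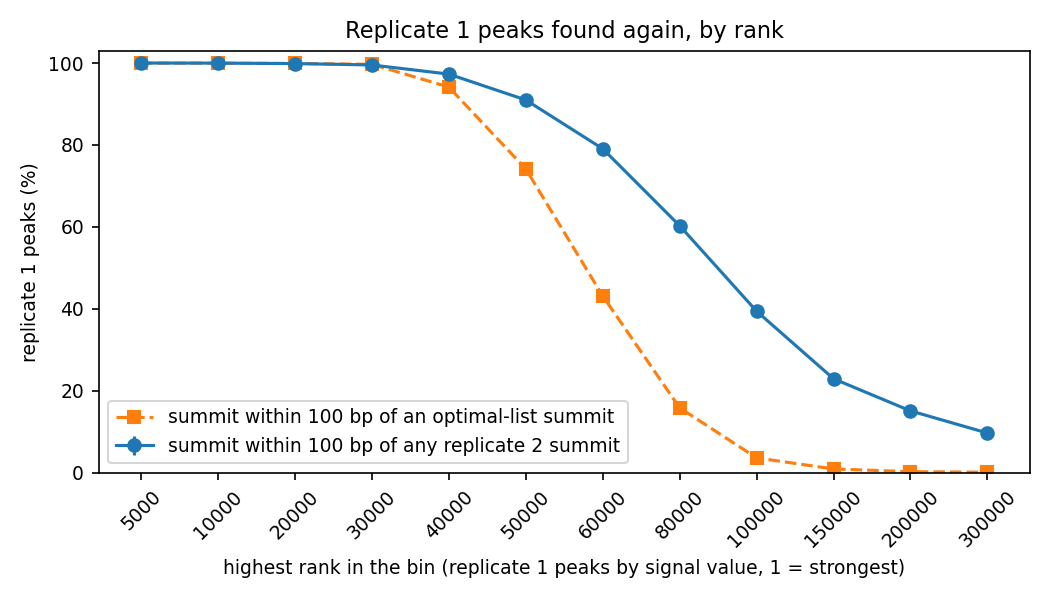
Share of replicate 1 peaks (y axis, percent) found in replicate 2 or in the optimal list, by rank of their signal value (x axis, highest rank of each bin, bins of unequal width; bars are Wilson 95% intervals, mostly smaller than the points). The share found in replicate 2 is 99.5% in ranks 20001 to 30000 and 79.1% in ranks 50001 to 60000.

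Single sites differed between the replicates by much more than the rest. The SD of the log2 ratio of replicate 1 to replicate 2, centred on its median, was 0.50 over all 56235 sites, 0.26 in the stronger part of the list and 0.66 in the weaker part. The site nearest Xkr4 (chromosome 1, 3672382 to 3672681) had 3.51 in replicate 1 and 33.2 in replicate 2, a centred log2 ratio of -3.44. Sites in an intron of Pvt1, near Mvb12b and at the promoters of Rpf1 and Sgf29 were also higher in replicate 2, with centred log2 ratios from -2.89 to -2.63. In the other direction, the site in an intron of Eif3k (chromosome 7, 28973115 to 28973414) had 34.8 in replicate 1 and 2.95 in replicate 2. Sites at Map4 and near Sfrp2 had centred log2 ratios of 2.95 and 2.85. The ratios of 3.84 at Tesk1 and 3.22 at 2700038G22Rik came from a stronger overlapping neighbour in replicate 1. With the nearest summit in its place, replicate 1 had 42.1 at Tesk1 and 12.7 at 2700038G22Rik, against 10.2 and 10.7 in replicate 2. With 1 library on each side these differences have no test.

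The optimal and the conservative lists shared most sites, and those found in 1 list alone were weaker. Both lists passed the authors' irreproducible discovery rate (IDR) threshold, though 89 placed optimal-list peaks overlapped no called peak of replicate 1 and 139 none of replicate 2. The conservative list had 54779 peaks, and 49036 peaks had identical coordinates in both. Of the optimal list, 87.4% (Wilson 95% interval 87.1 to 87.6%) overlapped a conservative peak by 1 bp or more. The 7137 optimal-list peaks that did not had a median signal value of 22.1, against 80.3 for those that did. The 5487 conservative peaks outside the optimal list had a median of 21.9, so the conservative list was not a subset of the optimal one.

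CTCF sites were more frequent than by chance at promoters and in exons, and less frequent than by chance in intergenic DNA. Promoters, taken as 1 kb on each side of the TSSs of protein-coding genes, held 16.6% of the 56462 summits (Wilson 95% interval 16.3 to 16.9%), 7.59 times the 2.18% ± 0.0895 (SD) of 1000 circular shifts. Exons held 5.95%, 1.62 times chance, and intergenic DNA 34.1%, 0.668 times chance. Each of these had p = 0.002 by the 2-sided permutation, the smallest it can give. Introns held 43.3%, against 43.1% by chance, with permutation p = 0.64. In the stronger part of the optimal list promoters held 13.1% of summits, still 6.02 times chance. Of 21910 protein-coding genes, 8070 (36.8%) had a summit within 1 kb of a TSS, and of 10139 long noncoding RNA genes 1696 (16.7%) did. The share rose with the GC content of the TSS window, from 2.06% in the lowest decile of genes to 59.3% in the highest.

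The X chromosome had few CTCF sites for its length. It held 1304 optimal-list peaks, 7.98 per Mb of sequenced bases, and the autosomes 55157 peaks, 23.02 per Mb. The ratio of X to autosomes was 0.346, with an exact 95% interval of 0.328 to 0.366. Among autosomes the density went from 17.7 per Mb on chromosome 3 to 34.8 per Mb on chromosome 11. The Y chromosome held 1 peak, with a signal value of 78.9. Soft-masked repeats made up 46.8% of X bases, 33.5% of autosomal bases and 96.3% of Y bases. The sex of the animals was not collected, per the labels.

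**Figure D2:**
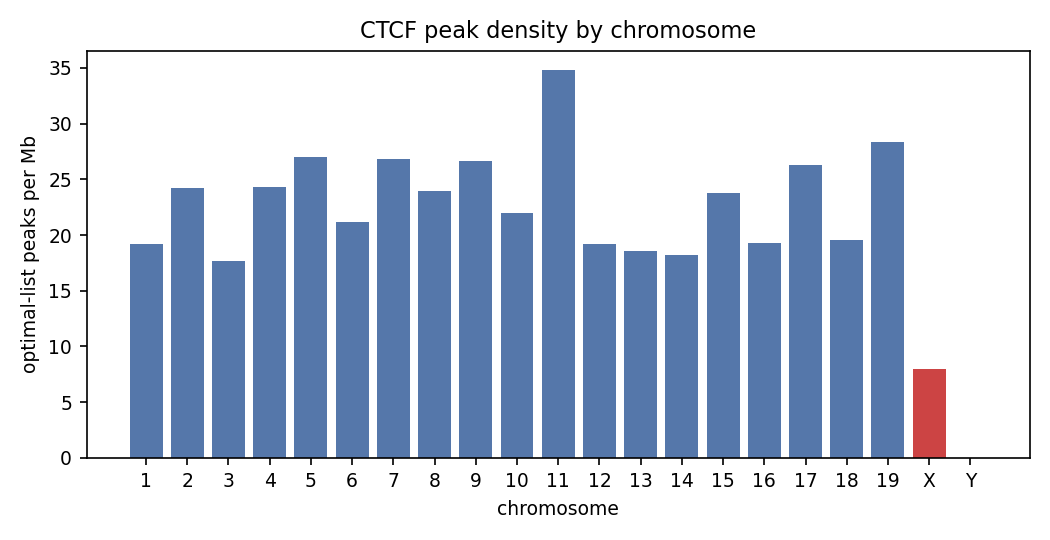
Optimal-list peaks per Mb of sequenced bases (y axis) on each chromosome (x axis), autosomes in blue and sex chromosomes in red. The X chromosome, at 7.98 per Mb, lies below every autosome, and the lowest autosome is at 17.7 per Mb.

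Most sites carried the CTCF motif, and the strongest sites nearly always did. Of 56462 optimal-list peaks, 37986 (67.3%, Wilson 95% interval 66.9 to 67.7%) had a match to CCASYAGRKGGCRS with at most 2 mismatches within 50 bp of the summit. Windows 1000 bp upstream and downstream of the same summits had one in 3.36% and 3.47%. A match at the summit and not upstream was found for 36720 peaks and the reverse for 631, and by the exact sign test p was below the smallest number the computation could hold. The centre of the match lay a median of 6.5 bp from the summit. The share with a motif rose from 38.8% in the weakest decile of the list to 91.7% in the strongest.

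Sites with the motif had higher signal values than sites without it, with medians of 92.1 and 38.4. The mean log2 signal value was 6.50 with the motif and 5.49 without, a difference of 1.01 ± 0.011 (SE), with p = 1e-05 by a 2-sided permutation test across peaks, the smallest it can give. The difference was 0.95 in replicate 1 and 0.98 in replicate 2. The median signal value was 207 at 5346 peaks with 0 mismatches, 109 at 1 mismatch, 59.8 at 2 and 42.6 at 3.

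Promoter sites were weaker than other sites and less often had the motif. Their mean log2 signal value was 5.83, against 6.23 elsewhere, a difference of -0.41 ± 0.015 (SE) with p = 1e-05 by the same permutation test, again the smallest it can give. The difference was -0.31 in replicate 1 and -0.38 in replicate 2. The motif was found at 37.0% of 9355 promoter peaks, 66.4% of exonic, 72.4% of intronic and 75.6% of intergenic peaks. Among the peaks with the motif the difference in strength was no longer detectable: promoter sites had 6.52 and other sites 6.50, with permutation p = 0.26, in a comparison chosen after seeing the data. Among peaks without the motif, a split also chosen after seeing the data, a small difference of -0.10 ± 0.019 (SE) remained, with permutation p = 1e-05.

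**Figure D3:**
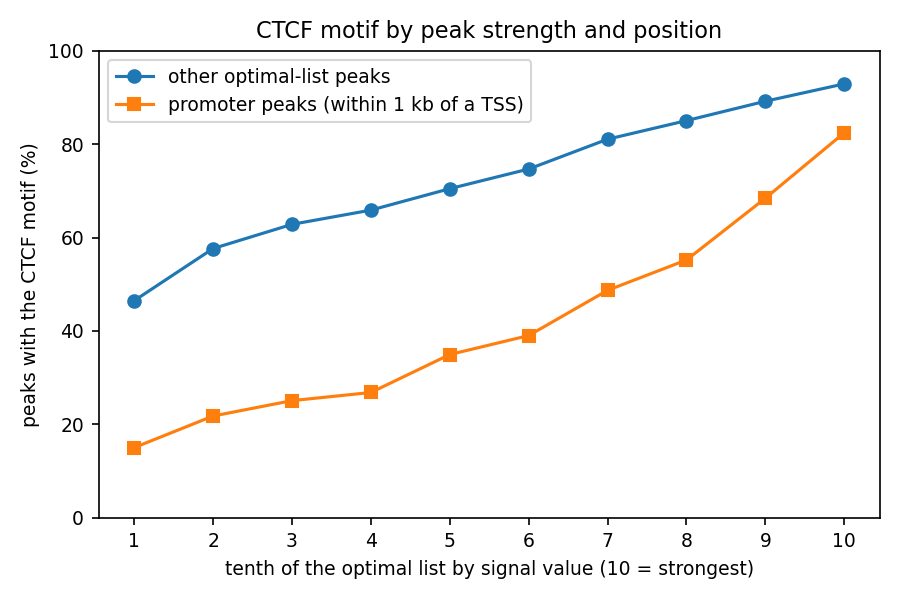
Share of optimal-list peaks with the CTCF motif (y axis, percent) in each decile of the list by signal value (x axis, 10 the strongest), for promoter peaks and other peaks. In the weakest decile the shares are 15.03% and 46.5%, and in the strongest 82.4% and 92.9%.

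The genes with CTCF at their promoters were not a random sample, and 6 of the 16 preset lists differed from all other genes at an adjusted p of 0.05. Clustered protocadherins, cell-surface proteins that give neurons individual identities, had a summit within 1 kb of a TSS in 24 of 38 genes (63.2%), against 30.4% of other genes (Fisher's exact test, 2-sided, Benjamini-Hochberg over the 16 lists, adjusted p = 0.000263). Pcdhac1 had the strongest site, 305 (chromosome 18, 37089832 to 37090088), 50 bp from its TSS, followed by Pcdhgc3 with 107 and Pcdha9 with 69.0. Most others were weak: when only the stronger part of the optimal list was counted, 7.89% of these genes had a site, fewer than the 14.3% of other genes, and the list was not called. It stayed called against GC-matched lists, which had 11.3% (permutation adjusted p = 0.00107). Neuronal activity and synapse genes had a site in 24 of 39 (61.5%; Fisher's exact test, adjusted p = 0.000285). Grin2a, an NMDA receptor subunit, had 351 (chromosome 16, 9993768 to 9994021), Nrxn2, a presynaptic adhesion protein, 350, and Egr1, an activity-induced transcription factor, 330. This list was not called against random lists matched on GC content (45.3% expected, permutation adjusted p = 0.115), nor with 1 TSS per gene (43.6%, exact adjusted p = 0.111).

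The list of CTCF, cohesin and associated factors, among them Yy1 and Zfp143, had sites in 12 of 20 genes (Fisher's exact test, adjusted p = 0.0176). Stag1, a cohesin subunit, had 429 in its UTR (chromosome 9, 100643408 to 100643737), with the motif match CCAGCAGAGGGCGG of 0 mismatches, and Pds5b and Esco1 had 328 and 298. Ctcf itself had 79.4. Against GC-matched lists, where 52.1% were expected, this list was not called (permutation adjusted p = 0.754), nor was it with the conservative list (exact adjusted p = 0.0501) or among protein-coding genes only (0.0858, exact), a background chosen after seeing the data.

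Receptor genes of the olfactory and vomeronasal organs had almost no called CTCF summit near their annotated TSSs. Peak lists do not show whether reads could be placed in these gene families, so missing binding and missing reads cannot be told apart. Of 1092 olfactory receptor genes 8 (0.733%) had a site, against 31.5% of other genes (Fisher's exact test, adjusted p = 2.21e-158), and of 331 vomeronasal receptor genes 2 (0.604%) did (adjusted p = 3.9e-48, exact). The gap was smaller against GC-matched lists, which had 4.85% for olfactory receptors (permutation adjusted p = 0.00107) and 2.75% for vomeronasal receptors (permutation adjusted p = 0.0269). Olfr557 had the strongest, 215 (chromosome 7, 102695478 to 102695684), then Olfr556 with 128 and Olfr156 with 125. The 2 vomeronasal receptors, Vmn1r27 and Vmn1r20, had 23.7 and 20.4. None of 20 liver genes had a site (Wilson 95% upper limit 16.1%; adjusted p = 0.00322, exact), but the list was not called with a window of 5 kb, where 5 of 20 had one (exact adjusted p = 0.127), or with the stronger part of the optimal list, where the share was again 0% against 14.3% of others (exact adjusted p = 0.269). Against GC-matched lists, which had 27.1%, it stayed called (permutation adjusted p = 0.0104).

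The remaining 10 lists did not pass the exact test. Hox genes, which set position along the body axis, had sites at 6 of 39 promoters (15.4%, adjusted p = 0.107, exact). Hoxb5 had 232, Hoxc5 212 and Hoxa5 143. Against GC-matched lists, which had 48.7%, the Hox share was lower (permutation adjusted p = 0.00107). With a window of 5 kb the direction turned, to 59.0% of Hox genes and 46.4% of others (exact adjusted p = 0.236), and among protein-coding genes only, a background chosen after seeing the data, the list was called as lower (exact adjusted p = 0.0118). Imprinted genes, expressed from 1 parental copy, had sites at 19 of 41 (46.3%, adjusted p = 0.0911, exact). This list was called with windows of 500 bp (exact adjusted p = 0.0155) and 5 kb (0.000873, exact) and with each replicate alone (0.0162 and 0.0246, exact), but not against GC-matched lists, which had 41.0% (permutation adjusted p = 0.754). H13 had 424, Mest 188 and Gnas 172. Forebrain transcription factors had sites at 15 of 40 (37.5%), with Bcl11b at 152, Bcl11a at 134 and Cux2 at 120. Housekeeping genes had sites at 13 of 30, with Rplp0 at 414, Rpl13a at 292 and Actb at 261. This list was called with a window of 5 kb (exact adjusted p = 0.0275) and without replicate 1 (0.0198, exact), but not against GC-matched lists, which had 43.0%. Progenitor and astrocyte genes had 6 of 20, with Nes at 204, Slc1a2 at 95.1 and Hes5 at 39.3. Oligodendrocyte lineage genes had 5 of 15, with Myrf at 228, Pdgfra at 218 and Cnp at 58.7. Among markers of other cell types, microglia genes had 3 of 15, with Irf8 at 48.9 and C1qa at 44.3, and endothelial and pericyte genes 3 of 15 (Slc2a1, Esam and Ocln). Erythroid genes had 2 of 15, with Epor at 49.3. Of the X inactivation and X repeat loci, Xist with 164, Ftx with 138 and Firre with 79.7 had a site, 3 of 9.

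Of the 22 preset regions, 3 held more CTCF summits than 95% of random windows of the same length on the same chromosome. Firre, a long noncoding RNA gene on the X chromosome (50555744 to 50635321), had 23 summits, 28.9 per 100 kb (exact Poisson 95% interval 18.3 to 43.4), against 1.01 in random windows. These sites had a median signal value of 58.7, and 4 of them had the motif. The protocadherin gamma cluster (chromosome 18, 37661793 to 37841873) had 20 summits, 11.1 per 100 kb (6.78 to 17.2), against 2.13. The alpha and beta clusters had 13 and 14 summits, 5.05 and 5.39 per 100 kb, at the percentiles 93.0 and 94.3. Every motif match in the alpha cluster (6) and the beta cluster (3) was on the + strand, and the 1 match in the gamma cluster, in the UTR at its end, was on the − strand. The Xist locus, from which X inactivation is directed, had 6 summits, 3.67 per 100 kb (1.35 to 7.99), at the percentile 95.6.

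**Figure D4:**
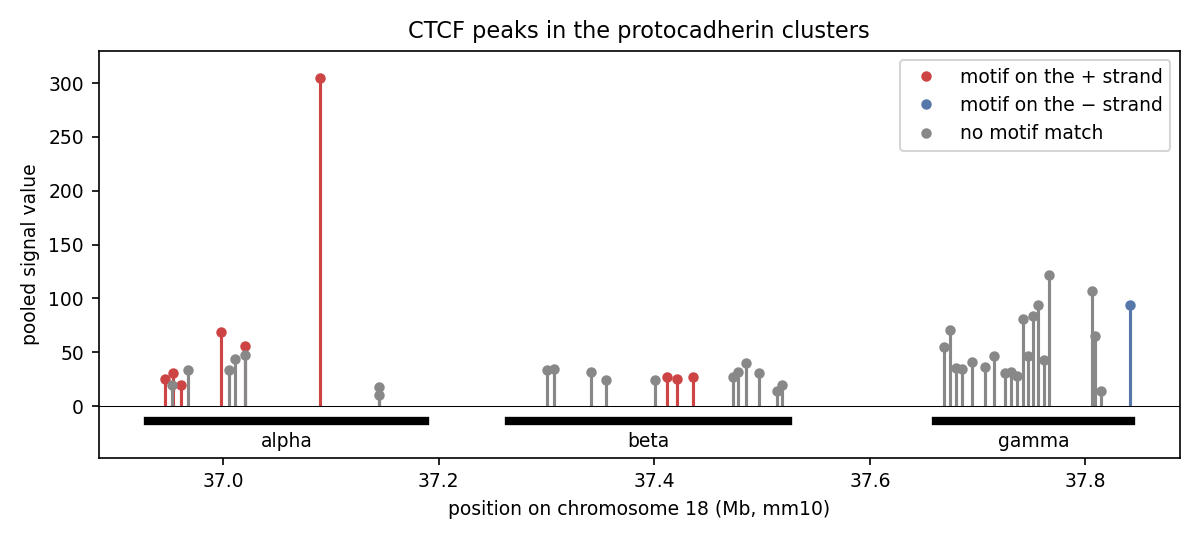
Pooled signal value (y axis) of each optimal-list peak in the protocadherin alpha, beta and gamma clusters by position on chromosome 18 (x axis, Mb, mm10), coloured by the strand of the motif match. The site at Pcdhac1 reaches 305, and the strongest in the beta cluster has 39.98.

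Hox clusters had from 4 to 10 summits each, at percentiles from 65.2 to 88.3, and their median signal values, 145 to 172, were above the 64.3 of the whole list. In the Hoxa cluster the strongest site, 407, was in an intron of Hoxa7 with its summit at 52221812 on chromosome 6. The Igf2 and H19 locus had 6 summits, 5 of which lay between 1131 and 3865 bp from the TSS of H19. The Dlk1 and Meg3 locus had 6 summits, with the strongest, 213, in an intron of Meg3. The Kcnq1 locus had 4 summits, and the strongest, 336, was in an intron of Kcnq1. The Snrpn and Ube3a locus had 4 summits in 911 kb, 0.439 per 100 kb (0.12 to 1.12), against 2.67 in random windows, at the percentile 15.4. The beta-globin cluster had 0 summits in 40.7 kb. Around genes of forebrain development, Sox2 and Emx2 had 9 summits each, Dlx1 and Dlx2 7, Dlx5 and Dlx6 6 and Pax6 5, at percentiles from 51.1 to 89.1. Bdnf, a neurotrophin gene, had 7 and Myc 6. A site near Emx2 had 354, in an intron of Emx2os, and one 52270 bp from Dlx2 had 333.

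**Figure D5:**
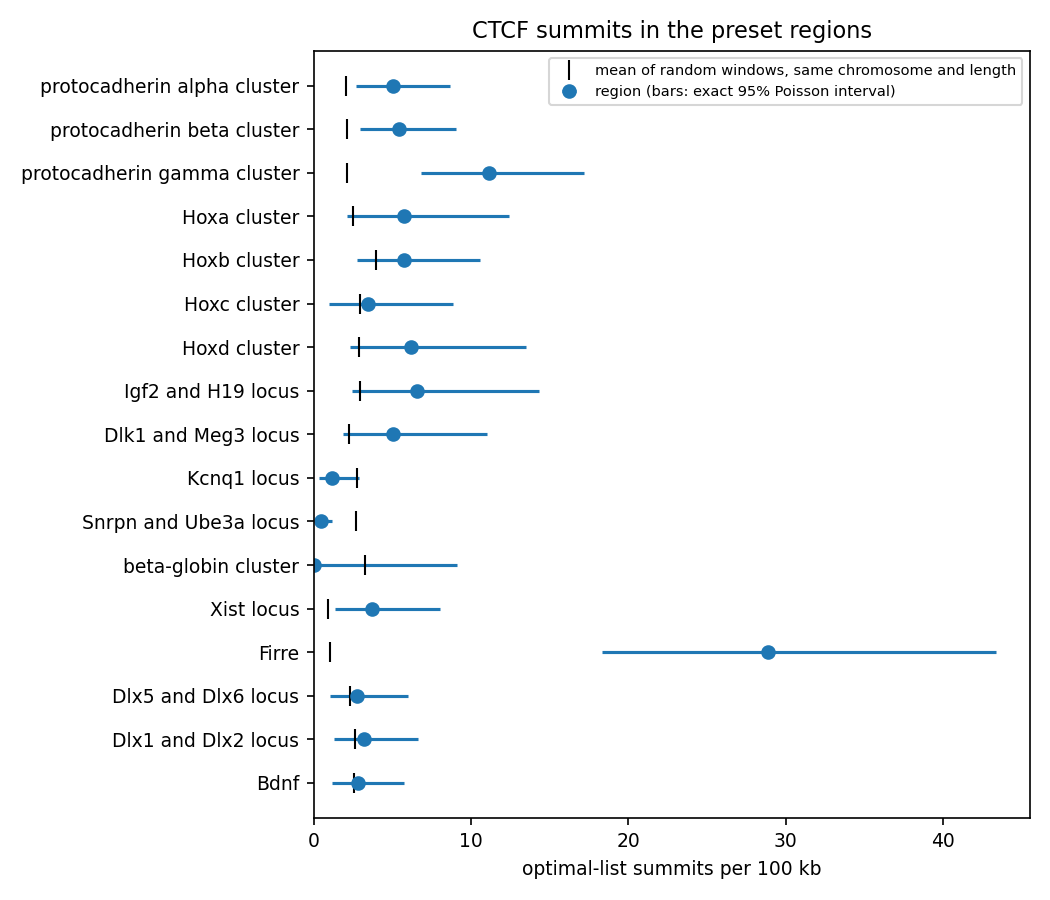
Optimal-list summits per 100 kb (x axis) in most of the preset regions (points; bars are exact 95% Poisson intervals) and the mean of random windows of the same length and chromosome (ticks). Firre, at 28.9 per 100 kb, lies farthest from its random windows, at 1.01.

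Neighbouring motifs 10 kb to 1 Mb apart were arranged back to back slightly less often than by chance. Of 26802 neighbouring pairs, 23.1% were divergent, -1.93 percentage points from the mean of strand shuffles (SD of the shuffles 0.190). Convergent pairs, which face each other, made up 25.7%, 0.716 percentage points above the shuffles, and tandem pairs 51.2%, 1.22 above. Each had p = 0.002 by the 2-sided permutation of strands, the smallest it can give. The excess of tandem pairs turned into a deficit, 49.2% (permutation p = 0.048), with at most 1 mismatch in the motif, and the excess of convergent pairs was lost, at 24.8%, for pairs up to 200 kb apart. The deficit of divergent pairs shrank to -0.635 percentage points (permutation p = 0.01) and -1.18 in these settings.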

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

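The test on peaks with a q-value over 0.05 was chosen after such peaks had been seen beside strong ones, as was its comparison with other weak peaks, and the comparisons of X signal, of bound motifs and of motifs with 0 mismatches on the X were also added after the results were seen.

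The pooled list held 7 peaks at or above the median signal value of the optimal list that were in neither IDR list, a signal in data the comparisons did not use. The strongest had 252 (chromosome 1, 195241467 to 195241687), with 130 in replicate 1 and 122 in replicate 2, and 6 of the 7 had the motif. The optimal list also held 8 peaks on unplaced contigs, with signal values from 14.6 to 459.

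The X chromosome had 0.346 times the autosomal density of peaks. Motif matches were less sparse than that, at 0.787 times the autosomal number per Mb with at most 1 mismatch (exact 95% interval 0.760 to 0.815) and 0.554 times with 0 mismatches (0.485 to 0.630), which argues against motif content as the whole cause and leaves it open as a part. Counting only bases and summits outside soft-masked repeats left a ratio of 0.455 (0.429 to 0.483), so the soft-masked share alone does not account for it either. Peak lists do not show whether reads could be placed in the remaining bases, so sites hidden there cannot be told apart from missing ones. The median signal value on the X was 0.527 times the autosomal one at peaks with 0 mismatches (bootstrap 95% interval 0.441 to 0.637) and 0.661 times at peaks with at most 1, but 61.6 against 64.4 over all peaks, and 47.7% of motifs with 0 mismatches were bound on the X against 83.0% on autosomes. A lower number of X copies cannot be told apart: sex was not collected, and though halving autosomal signal values left 68.0% of peaks above the 5th percentile of the list, that assumes a linear scale that was not stated.

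Promoter peaks lacked the motif more often than other peaks. Weakness alone does not account for it, since the motif share at promoters was still lower within every decile of signal value. The mean difference was -30.9 percentage points (SD over the 10 deciles 8.85, a spread between deciles and not a counting error). It ranged from -39.0 in decile 4 to -10.5 in the strongest decile, so the gap was narrower among the strongest peaks. Whether the motif threshold missed weaker matches cannot be told apart: with 3 mismatches the excess over flanking windows differed by -20.9 percentage points, past the bound of 20 set beforehand, but an interval added after the value was seen, -22.0 to -19.7, spans that bound. The share without a motif was 13.3 percentage points higher in the most GC-rich of 3 equal groups of promoter peaks than in the least (10.9 to 15.7), so signal at GC-rich open promoters with no site of their own is a candidate explanation for a part only, since 55.2% lacked the motif even in the least GC-rich group, against 12586 of 47107 peaks outside promoters. A control library, not used here, would be needed to test it.

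The optimal list held 461 peaks with a q-value over 0.05, with a median signal value of 7.49, and 134 of them had the highest score. Of these 461 peaks, 93.5% (Wilson 95% interval 90.9 to 95.4%) had a stronger pooled-list summit within 500 bp, against 1.64% of the other optimal-list peaks and 5.55% of 197428 pooled peaks outside the list whose q-value was also over 0.05. They may have passed the threshold through their overlap with a strong neighbour, and 7.59% of them had the motif.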

How the results depend on the processing

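Of 328 recomputed values, 275 kept their direction and their side of the threshold or, with no test, stayed within their error or within 1.5 times a count. The share of the optimal list found in the conservative one was 86.8% with summits within 100 bp and 86.8% with reciprocal overlap of 50%. Spearman's rho was 0.962 for the conservative list, 0.956 above the median signal value and 0.940 with the nearest summit (added after seeing the data). Introns passed the test at 45.5% with promoters of 500 bp, and lay below chance, without passing, at 40.9% with promoters of 2000 bp and 42.3% with the stronger part of the list. Among peaks with the motif, the promoter difference was 0.026 (added after seeing the data). Tandem pairs fell to 49.2% with at most 1 mismatch and convergent pairs to 24.8% within 200 kb. Some gene lists changed direction against other genes, none of them past the threshold. With the stronger part of the list these were clustered protocadherins (7.89%), forebrain transcription factors (10%), housekeeping genes (10%) and oligodendrocyte genes (13.3%). With windows of 5000 bp these were Hox genes (59.0%), progenitor and astrocyte genes (60%) and microglia genes (46.7%), and with 500 bp forebrain transcription factors (22.5%) and X loci (22.2%). Oligodendrocyte genes did so with the conservative list (26.7%), among protein-coding genes (33.3%) and against GC-matched lists (33.3%), as did forebrain transcription factors against GC-matched lists (37.5%). With 1 TSS per gene these were forebrain transcription factors (25%) and progenitor and astrocyte genes (30.0%), and among protein-coding genes X loci (0%), both settings added after seeing the data. With each replicate alone, progenitor and astrocyte genes had 25 to 35%, oligodendrocyte genes 26.7 to 33.3% and X loci 22.2 to 44.4%. The cause was not tested for any of these changes. Of 248 values for single gene lists and regions, 7 lost their call in the same direction, 8 gained one, 19 changed direction (clustered protocadherins losing their call as well) and 8 region densities fell by more than their error with the stronger part of the list, which holds fewer peaks. With each replicate alone, the motif share was 66.4 to 66.7%, the X ratio 0.345 to 0.348 and the number of called gene lists 7 to 8. Called lists numbered 4 to 8 over all alternatives, and the lists called were not always the same. Olfactory and vomeronasal receptor lists stayed called in every alternative. Peak lists carry no read counts, so depth behind single values is unknown.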

Other observations

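The test of the soft-masked share, and the choice of the intervals to describe, came after the results were seen.

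Called CTCF summits were dense in some intervals and missing from others. The densest 100 kb bins each held 20 summits: one on chromosome 10 (80100001 to 80200000) with Stk11, Midn, Cirbp and Efna2, one on chromosome 4 (148100001 to 148200000) with Draxin, Mad2l2 and Fbxo2, and one on chromosome 7 (79500001 to 79600000) with Rhcg. Stretches without a summit were searched between neighbouring summits of the autosomes and the X, leaving out those with many unsequenced bases. The Y chromosome, which held 1 peak, was not searched. The longest stretch found was 5.18 Mb on chromosome 7 (7299732 to 12478206), where 42 of 55 protein-coding genes were olfactory or vomeronasal receptors. Another on chromosome 7 was 4.20 Mb long and held 65 receptors among 108 genes, and one on chromosome 17 was 3.05 Mb long and held 30 among 36. A stretch of 4.36 Mb on the X chromosome (115929640 to 120285735) held 6 protein-coding genes, among them Pabpc5. Stretches on chromosome 11 with Vstm2a and on chromosome 13 with Edil3 were 3.27 and 3.10 Mb long and held no receptor gene.

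The most frequent motif sequence was CCAGAAGAGGGCAT, found at 1906 of 37986 motif-bearing peaks (5.02%). These peaks were weak, with a median signal value of 36.6 against 98.0 for other motif-bearing peaks. All of the matches, 100%, lay in soft-masked bases, against 16.0% of other matches, so these sites may come from a family of repeats. The sequence around the copies gave no clear answer: the 50 bp on each side were 37.1% identical between copies, above the 26.0% of other matches but between the bounds of 35% and 50% set beforehand. The comparison allowed no gaps, which old repeat copies would need. Soft-masking and low signal were not particular to 1 sequence. The sequences next in frequency, at 1045, 586, 513 and 323 peaks, differed from the most frequent one only in their last bases. Between 99.5% and 100% of their matches were soft-masked, and their median signal values ran from 34.9 to 51.2. They were counted among the other matches above, so the share of 5.02% covers only a part of this group.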
